A study of Mus musculus with 10 samples.

How the data were processed

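The series measured 4 histone marks by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse neutrophils that were sorted and not cultured. The labels give 1 library per mark and genotype, for wild-type C57BL6 mice (WT) and for mice of the same background deficient in the long non-coding RNA Morrbid (KO). Per the labels' protocols, nuclei were sonicated, histone-DNA complexes were isolated with antibodies, and libraries were made with a KAPA Hyper Prep Kit. Of the 10 samples, 8 are ChIP libraries of the marks H3K4me1, H3K4me3, H3K27ac and H3K36me3. The other 2 are titled as input DNA, although their antibody field names normal rabbit IgG, and they were not used here.

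Per the submitters' processing notes, the tools were bcl2fastq 2.16.0, Trimmomatic 0.32, Bowtie2 2.2.3, MACS2 2.1.0, DiffBind, R 3.1.1 and HOMER, and the genome build was mm9. The notes give no order or settings of these steps, and whether input was subtracted is not given in the sources used here. Each of the 4 deposited tables lists the consensus peaks of 1 mark with a normalized read signal for the KO and the WT library, as the authors computed it. The deposited log2 fold column equals log2(KO/WT) of those signals, with a largest gap of 4.84e-08 over all peaks. In all 8 columns 100% of the deposited signals were whole multiples of the column's lowest value, within 0.01 of a read, so the lowest value is worth 1 read and whole reads could be recovered. No peak lies under 1 read, so a peak without reads and a peak with 1 read cannot be told apart. Peak annotations are those of the deposited tables. Gene symbols were matched to transcripts through a RefSeq table of another mouse assembly (GRCm38.p6), from which no coordinate was taken. Coordinates are mm9, 1-based, as deposited.

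The reads recovered inside peaks were 2438593 (WT) and 14317664 (KO) for H3K4me1, 2669490 and 10277795 for H3K4me3, 2250264 and 10265524 for H3K27ac, and 11618230 and 13095590 for H3K36me3. One read was therefore worth 3.40 normalized units in the WT and 0.592 in the KO for H3K4me1, and 1.07 and 0.935 for H3K36me3. A peak with 1 read in both libraries has a fixed log2(KO/WT) of -2.52 for H3K4me1, -1.86 for H3K4me3, -2.16 for H3K27ac and -0.20 for H3K36me3, whatever happened in the cells.

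The change of a peak or gene was computed as log2 of (KO + 1) over (WT + 1) on the deposited scale, minus the median of that value over all peaks of the mark. This fold is on the scale with the pseudocount of 1, which understates changes of low values. Because weak peaks weigh in that median, 0 is not the middle of strong peaks in every mark. For H3K4me3, autosomal peaks at or above the median value had a median of 0.14. A gene's value was the sum over its peaks: those within 5 kb of its transcription start for H3K4me3 and H3K27ac, those within 50 kb or in the gene body for H3K4me1, and those in the gene body for H3K36me3. Intervals are exact (Clopper-Pearson) 95% binomial intervals on the recovered reads of the 2 libraries. They cover counting error only, since PCR copies are not independent molecules and animals were not replicated. Where the KO was at its minimum, a lower bound of the fold was computed against 3 reads. With 1 library per group no residual degrees of freedom exist, so a count model (edgeR, DESeq2) could not be fitted to the recovered reads, no gene was called by such a test, and no p-value is given. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

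Each of 26 gene lists, 10 of them markers of cell types, was summarised per mark by the median change of its measured members. That median was placed among the medians of 10000 random lists of the same size, matched on mean value in 10 bins, and a median outside the central 95% of these is called beyond the random range. The lists, the grouping, the gene values, the fold rule of 2 and most alternatives were fixed before the data were examined. The rule for named genes, fixed at the same time, takes all peaks annotated to Acoxl, Bcl2l11, Gm14005, Anapc1 or Mertk. It also takes, per mark, the 10 genes with the highest and the 10 with the lowest change among genes at or above the median value, and for the lists led with, the 2 highest and 2 lowest members and any over 2-fold, although not every gene it takes is reported here. The limits of the deleted interval, the summary of Bcl2l11 by segments and its rank among genes of similar sum were chosen after the data had been seen.

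The steps were tested on simulated reads drawn from the real means and depths, with 200 upper-half genes changed per mark. Among H3K36me3 genes (10130 in the table) raised by a log2 of 1, the median estimate was 0.99 and 100% were found at least 1.5-fold higher. For H3K4me1 (18609 genes) the same true change gave a median estimate of 0.95 and 92% found. Its 95% intervals held the true value for 92% of unchanged genes. H3K4me1 genes lowered by a log2 of 1 had a median estimate of -0.87, and 84% were found. Genes raised and lowered by a log2 of 1 had median estimates of 1.09 and -0.92 for H3K4me3, and 1.11 and -0.90 for H3K27ac. Estimates of these 2 marks therefore leaned upward in the simulation. Unchanged genes beyond 1.5-fold numbered 27 of 9105 for H3K4me1, 0 of 6862 for H3K4me3, 10 of 5941 for H3K27ac and 0 of 4865 for H3K36me3. Coverage of the intervals was 88.2% for H3K4me3, 95.2% for H3K27ac and 94.5% for H3K36me3. For H3K4me1, changes were put in by nearest gene, whereas a gene's value also takes body peaks nearest to other genes. Its unchanged genes could therefore hold changed peaks, so its recovery, counts and coverage do not measure counting error alone. Alternatives were other pseudocounts (10 and 0.1), other centrings, filters on low peaks, a fold rule of 1.5, autosomes only, other assignments of peaks to genes and, added later, removal of peaks at 1 read in both libraries, thinning of the KO reads to the WT number, and centring over genes of similar peak density.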

Results

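Morrbid is a long non-coding RNA encoded on mouse chromosome 2 near Bcl2l11, the gene of the pro-apoptotic protein Bim. The series title names Bim and the lifespan of short-lived myeloid cells as its subject. To ask how chromatin differs without Morrbid, 4 histone modifications were mapped in sorted neutrophils of WT and Morrbid-deficient (KO) mice, with 1 library per mark and genotype. H3K4me1 marks enhancers, H3K4me3 marks promoters, H3K27ac marks active promoters and enhancers, and H3K36me3 covers the bodies of transcribed genes. The consensus sets held 81980 H3K4me1 peaks, 53500 H3K4me3 peaks, 67733 H3K27ac peaks and 43255 H3K36me3 peaks. Depth was unequal for 3 marks, with 5.87 times as many reads in peaks in the KO as in the WT for H3K4me1, 3.85 times for H3K4me3 and 4.56 times for H3K27ac, against 1.13 times for H3K36me3. No difference below has a replicate check, and intervals give counting error between these libraries only.

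The targeted locus separated the genotypes as labelled. Morrbid, which the files call Gm14005, lost its marks in the KO. On chromosome 2 (mm9) between positions 128074258 and 128255852, a stretch of 182 kb, all 55 peaks of the 4 marks lying wholly inside were at the KO minimum of 1 read, 15 for H3K4me1, 8 for H3K4me3, 13 for H3K27ac and 19 for H3K36me3. The longest other run of such peaks anywhere in the genome, counting peaks with at least 5 WT reads, was 2 peaks for H3K4me1 and 1 for each other mark. The highest WT peak inside, an H3K36me3 peak at 128138800 to 128157941 in intron 2 of transcript NR_028590, had 811 normalized reads and was at least 289-fold lower in the KO. An H3K4me3 peak at 128251398 to 128255852 in intron 1 of NR_028591 had 777 normalized reads in the WT and was at least 399-fold lower. An H3K4me1 peak at 128244504 to 128253403 was at least 444-fold lower, and an H3K27ac peak at 128197973 to 128201790 at least 171-fold lower. An H3K27ac peak at 128238887 to 128266064 spans the far edge and had 446 normalized reads in the KO against 1930 in the WT. The first peak wholly past the interval starts at 128255870, and the last peak with KO signal before it ended at 128073698.

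Summed over its peaks, Bcl2l11 carried more of every mark in the KO, most of all H3K36me3 and H3K27ac. The 2 H3K36me3 peaks in its body, at 127953886 to 127989457, summed to 1953 normalized reads in the KO and 958 in the WT, a 2.03-fold difference (log2 1.02, counting interval 0.91 to 1.14). H3K27ac at its promoter, at 127948476 to 127954544, was 499 against 275 normalized reads (log2 0.85, interval 0.56 to 1.17). H3K4me3 at the promoter, at 127948140 to 127954568, differed less, with 1579 against 1358 normalized reads (log2 0.20, interval 0.07 to 0.34). This interval holds 0.14, the median of autosomal H3K4me3 peaks at or above the median value. H3K4me1 around the promoter had a log2 of -0.16 with an interval of -0.49 to 0.19, a difference not detectable at this depth. Summed over all peaks annotated to Bcl2l11 outside the deleted interval, the log2(KO/WT) was 0.36 for H3K4me1, 0.27 for H3K4me3, 0.54 for H3K27ac and 0.94 for H3K36me3. Centred on the running median, the H3K4me3 value was 0.15 (0.03 to 0.27). The sum ranked 1 of 612 genes with a similar sum for H3K4me1, 185 of 1631 for H3K4me3, 1 of 1016 for H3K27ac and 1 of 3601 for H3K36me3. By the gene value fixed beforehand, Bcl2l11 ranked lower for 2 marks. Among genes at or above the median it was 434 of 9305 for H3K4me1 (log2 0.30) and 1025 of 7062 for H3K4me3 (0.20). It was 1 of 6141 for H3K27ac and 1 of 5065 for H3K36me3.

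The higher signal reached from Bcl2l11 to the near edge of the deletion and not past its far edge. Peaks between the end of the gene body and the interval had a log2 of 0.50 (interval 0.36 to 0.65) for H3K4me1, 0.91 (0.39 to 1.49) for H3K4me3, 0.63 (0.43 to 0.83) for H3K27ac and 0.60 (0.36 to 0.84) for H3K36me3. All 12 H3K4me1 peaks of this stretch, all 5 H3K4me3 peaks, 13 of 14 H3K27ac peaks and 14 of 15 H3K36me3 peaks lay above 0. Upstream of the promoter H3K4me1 had a log2 of 0.24 (0.10 to 0.38) and H3K27ac 0.29 (0.13 to 0.46). On the far side of the interval the values were -0.17 (-0.26 to -0.07) for H3K4me1, -0.16 (-0.51 to 0.20) for H3K4me3, -0.11 (-0.23 to 0.01) for H3K27ac and -0.06 (-0.21 to 0.09) for H3K36me3. Anapc1, a cell cycle ubiquitin ligase subunit further along, had an H3K36me3 log2 of -0.05 (-0.11 to 0.01). Peaks nearest to Acoxl, the neighbour before Bcl2l11, had 0.06 (-0.13 to 0.25) for H3K4me1 over 9 peaks and 0.31 (0.02 to 0.62) for H3K27ac. Other peaks in the body of Acoxl are nearest to Bcl2l11 and were counted upstream of its promoter. With body peaks included, the H3K4me1 gene value of Acoxl was 0.15 (0.04 to 0.26) over 22 peaks. These segments were set after the peak values had been seen.

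**Figure D1:**
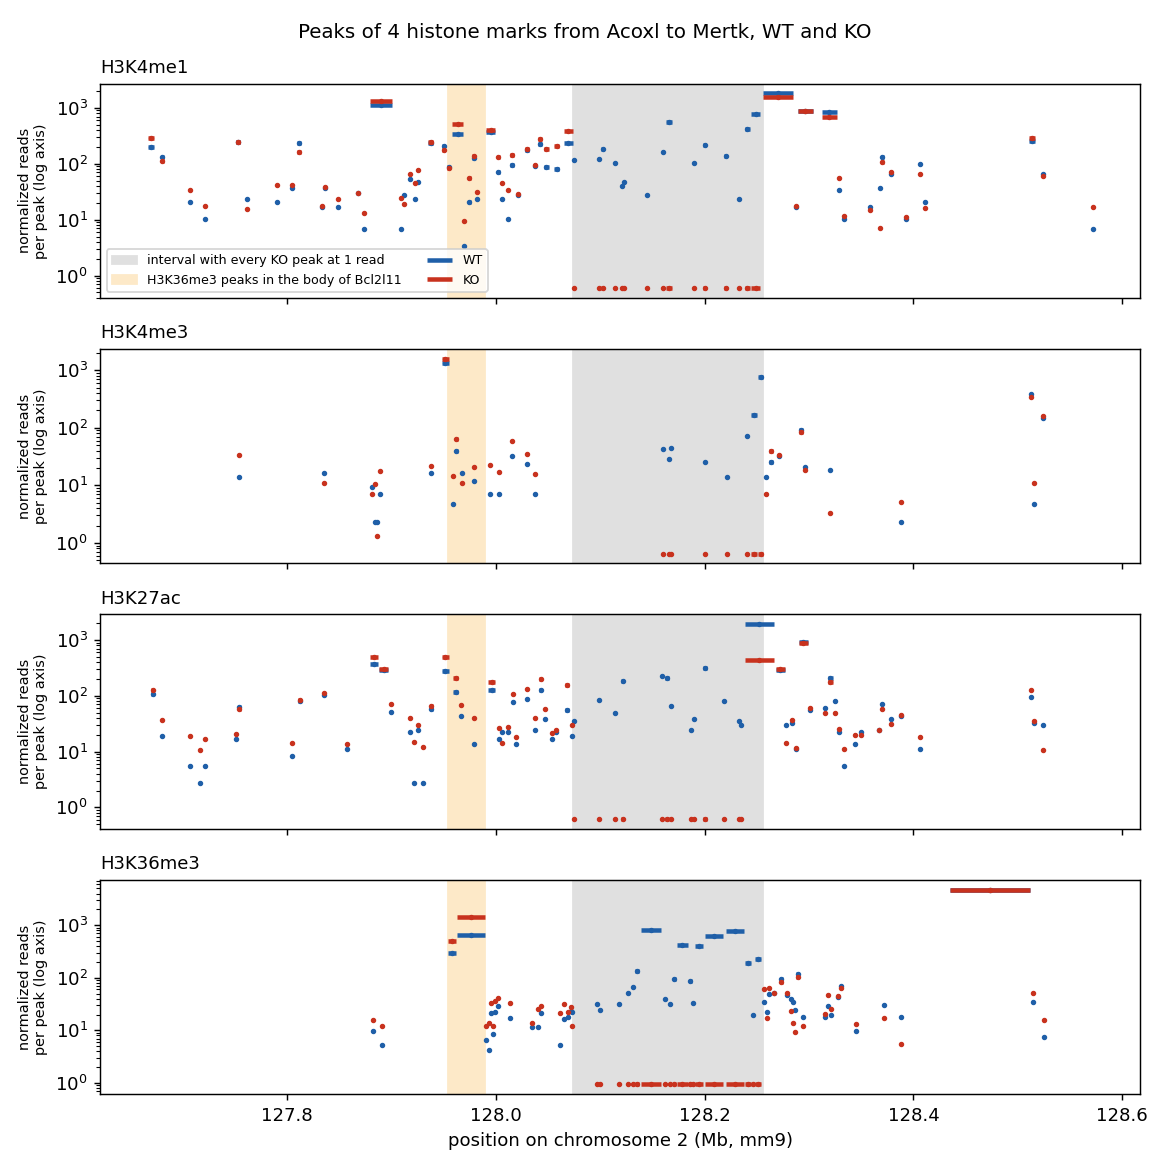
Normalized reads of each peak (log axis) against its position on chromosome 2 (Mb, mm9) for the 4 marks, WT in blue and KO in red, bars spanning the peak. In the grey interval all 55 peaks are at the KO minimum, and over the body of Bcl2l11 the H3K36me3 sum is 1953 in the KO and 958 in the WT.

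Across the genome, peaks with strong signal seldom differed by 2-fold between the genotypes. Among the 25% of peaks with the highest mean, 7 H3K4me1 peaks were at least 2-fold higher and 8 lower in the KO, of which 4 lay in the deleted interval. The counts were 21 higher and 18 lower for H3K4me3, 11 and 22 for H3K27ac, and 1 and 9 for H3K36me3, where 5 of the 9 lay in the interval. Over all peaks, 5538 were higher and 11045 lower for H3K4me1, 4676 and 13628 for H3K4me3, 4886 and 11005 for H3K27ac, and 1889 and 1874 for H3K36me3. Of the lower peaks, 60.9% for H3K4me1, 89.0% for H3K4me3 and 73.7% for H3K27ac were at 1 read in both libraries, where the ratio is fixed by depth. Centred on the running median over peaks of similar mean, the split became 3166 higher and 2087 lower for H3K4me1, 1279 and 2299 for H3K4me3, 2779 and 2779 for H3K27ac, and 616 and 2706 for H3K36me3. Simulated unchanged peaks of the same depths gave 3743 higher and 3677 lower H3K4me1 peaks, 1761 and 2127 for H3K4me3, 2822 and 4748 for H3K27ac, and 580 and 514 for H3K36me3. For the first 3 marks the simulated lower counts are under the 6723, 12126 and 8114 real peaks at 1 read in both libraries. The simulation therefore did not reproduce that floor, and its lower counts give no baseline for the lower peaks of these marks.

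In H3K36me3, the mark with even depth, Bcl2l11 had the highest value of the genes at or above the median. Among the 5065 genes at or above the median, 1 (Bcl2l11) was at least 2-fold higher and 1 (Gm14005) at least 2-fold lower, and 4 were at least 1.5-fold higher against 5 lower. Over all 10130 genes, those with few reads included, 162 were at least 2-fold higher and 115 lower. After Bcl2l11 came Lipg, encoding endothelial lipase, with a log2 of 0.89 (0.74 to 1.05), Dock9, an exchange factor of a small GTPase, with 0.83 (0.66 to 1.01), and Fam20c, a kinase of secreted proteins, with 0.62 (0.51 to 0.73). The intervals of Lipg and Dock9 overlap that of Bcl2l11 (0.91 to 1.14). The rest of the highest 10 were Cmah, a sialic acid hydroxylase, with 0.54, Bcl3, a nuclear cofactor of NF-kB, with 0.42, A530046M15Rik with 0.39, Arhgap18 and Csf2rb2 with 0.38 each, and L3mbtl3 with 0.37. Gm14005 was lowest, with all its 16 peaks at the KO minimum and the strongest at least 289-fold lower. Gabbr1, a subunit of the GABA-B receptor, followed with -0.98 (-1.17 to -0.80), then Thbs1, encoding a thrombospondin, with -0.79 (-0.94 to -0.65). Next were Trpm2, a cation channel, with -0.62, Ctse, encoding cathepsin E, with -0.58, Amica1, a leukocyte adhesion molecule, with -0.57, Sema4f with -0.56, the mitochondrial iron importer Slc25a37 with -0.56 and Cd101, a surface protein of mature neutrophils, with -0.55. Rn45s, the ribosomal RNA precursor, had -0.62, an uncertain value because its copies are repeated in the genome.

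In H3K4me3, Upp1, Gp49a and Lipg had the highest values of the genes at or above the median, and Nlrp3 and Cd101 were among the lowest. Of 7062 genes at or above the median, 0 were at least 2-fold higher and 2 lower (Gm14005 and Rn45s), with 22 and 32 at least 1.5-fold higher and lower. Over all 14124 genes, 368 were at least 2-fold higher and 444 lower. The highest were Upp1, encoding uridine phosphorylase, at 0.84 (0.61 to 1.08), Gp49a, an immunoglobulin-like receptor with near-identical relatives, at 0.80 (0.60 to 1.02), and Lipg at 0.78 (0.57 to 1.01). Upp1 also had an H3K36me3 log2 of 0.60 (0.40 to 0.80) and an H3K27ac log2 of 1.06 (0.42 to 1.80). Others were Celsr3, Prtn3 and Abca13 at 0.75, Olr1, a scavenger receptor, at 0.72, Ankrd22 at 0.69 and Emilin1 at 0.68. Prtn3 encodes a protease of the primary granules. On the other side were 3110070M22Rik at -0.96, Hdac7, a histone deacetylase, at -0.80, Fbxl17 and Npepl1 at -0.79, Nlrp3 at -0.77 (-1.02 to -0.52), Lemd2 and Kcmf1 at -0.73 and Cd101 at -0.70 (-0.94 to -0.45). Nlrp3, the inflammasome sensor, was also lower for H3K27ac, at -0.54 (-0.71 to -0.37), for H3K4me1, at -0.34 (-0.56 to -0.12), and for H3K36me3, at -1.35 (-1.58 to -1.14). Cd101 had -0.04 (-0.28 to 0.22) for H3K27ac.

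In H3K27ac, Bcl2l11 had the highest log2(KO/WT) of the genes at or above the median. Of 6141 such genes, 0 were at least 2-fold higher and 2 lower (Gm14005 and Nat8l), with 56 and 50 at least 1.5-fold higher and lower. All 12281 genes together gave 262 at least 2-fold higher and 512 lower. Bcl2l11 at 0.85 was followed by Nup214, a nuclear pore protein, at 0.84 (0.48 to 1.23), Smim15 and Gm2762 at 0.81, Zfp595 and the tRNA exporter Xpot at 0.80, Prmt10 at 0.79, Man2a2 at 0.77, Wdr7 at 0.76 and Cd14, the lipopolysaccharide co-receptor, at 0.75 (0.33 to 1.20). The intervals of these genes overlap that of Bcl2l11. Of the 9 besides Bcl2l11, Nup214 had -0.24 and Man2a2 -0.39 for H3K4me3. Among the lowest after Gm14005 were Nat8l, an acetyltransferase gene, at -1.14 (-1.53 to -0.76), Dlg1 at -0.99, Pbx3 at -0.97, Mir6950 at -0.91, Mir203 and Pwwp2a at -0.87, Zbtb17 at -0.85 and Atf3, a stress-induced transcription factor, at -0.79 (-1.09 to -0.50). For H3K4me3, Nat8l and Dlg1 had -0.45 each, whereas Atf3 had 0.24 (0.05 to 0.44). The interval of Atf3 holds 0.14, the median of autosomal H3K4me3 peaks at or above the median value.

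In H3K4me1, few genes with strong signal differed by 1.5-fold. Of 9305 genes at or above the median, 0 were at least 2-fold higher and 3 lower, with 12 and 17 at least 1.5-fold higher and lower. Among all 18609 genes, 301 were at least 2-fold higher and 1302 lower. Of 9105 simulated unchanged genes at or above the median, 10 were beyond 2-fold and 27 beyond 1.5-fold. These simulated genes could hold body peaks changed for another gene, so the counts do not show what counting error alone gives. The 3 genes at least 2-fold lower were Mir101c at -2.03, from a single broad intergenic peak near the start of chromosome 9, G530011O06Rik at -1.53 and Gm14005 at -1.06 (-1.14 to -0.97), whose peaks partly lie beyond the deletion. Mir6950 at -0.84 and Loxl2, a lysyl oxidase gene, at -0.81 (-0.95 to -0.66) lie together on chromosome 14. Loxl2 also had an H3K36me3 log2 of -1.92 (-2.14 to -1.71). Rn45s had -0.85, 4933422A05Rik -0.77, Csad -0.73, Ppm1k -0.69 and Tardbp -0.68. The highest were Rnf152 at 0.78 (0.41 to 1.19), Steap3, an iron reductase, at 0.70, the lymphocyte adaptor Lax1 at 0.69, 5430435G22Rik at 0.66, Fam175a at 0.65, A930005H10Rik at 0.63, Rgsl1 at 0.61, and Rnaseh2a, Topaz1 and Tmem89 at 0.60. With the KO thinned to the WT reads, Fam175a had 0.17 and Topaz1 0.16. Each of the highest 10 but 5430435G22Rik rested on 82 or fewer WT reads.

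**Figure D2:**
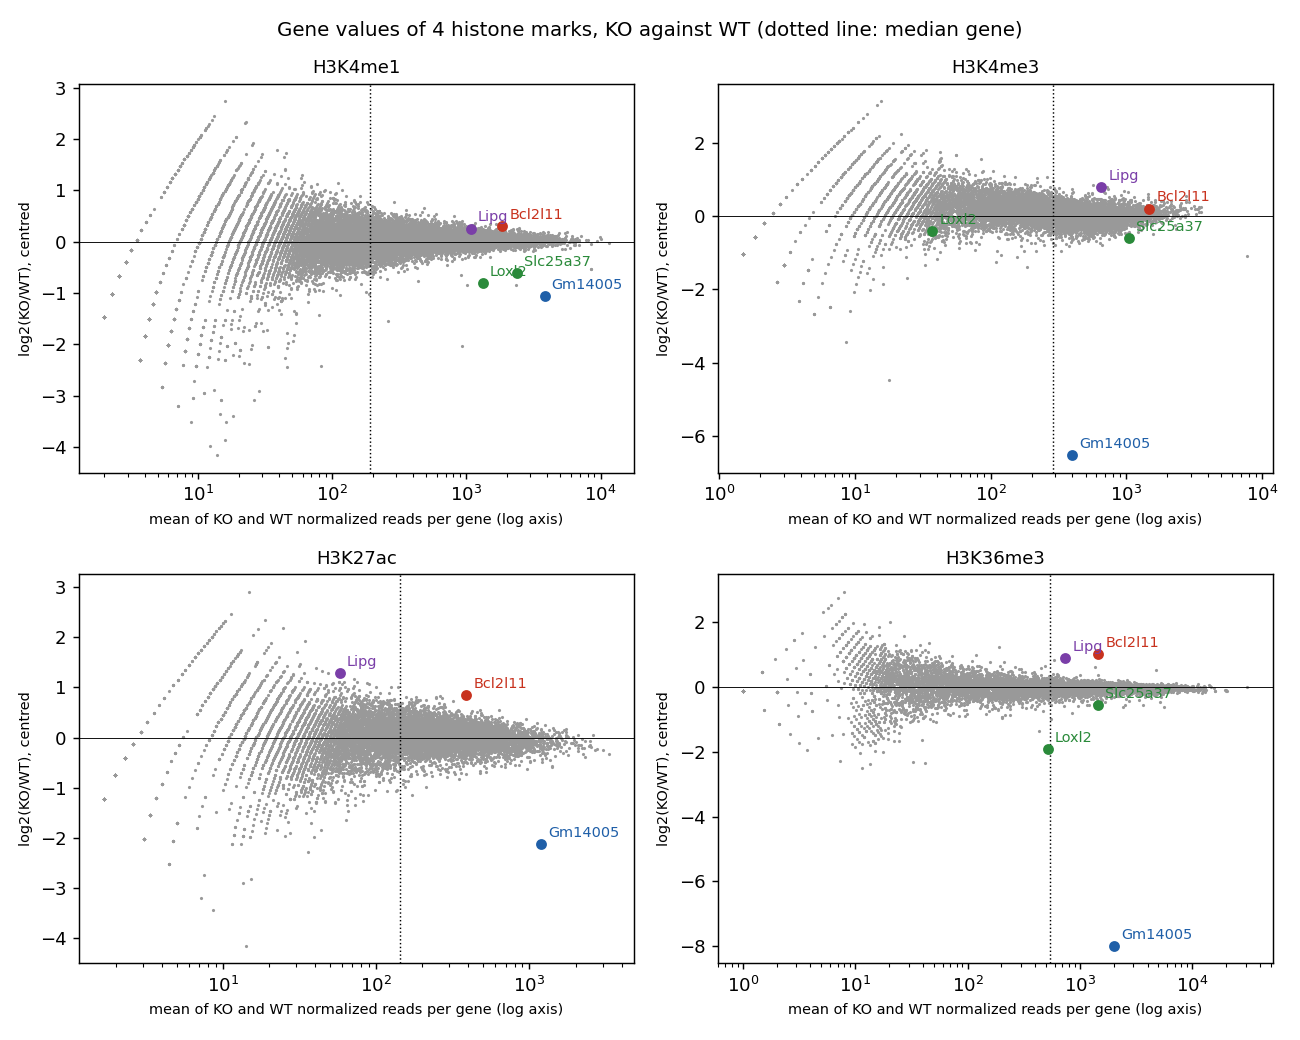
Centred log2(KO/WT) of each gene against the mean of its KO and WT normalized reads (log axis), one panel per mark, with the median gene as a dotted line. For H3K36me3, Bcl2l11 lies at 1.02 with Lipg next below at 0.89, and the place of Gm14005 is set by the KO minimum of 1 read per peak.

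Of the pro-apoptotic BCL2 family genes, Bcl2l11 had the highest H3K36me3 value, and Bak1 the highest for H3K4me3, at 0.30 (0.10 to 0.51) against 0.20 for Bcl2l11. The median of the pro-apoptotic list was within the random range for all 4 marks, at 0.00 (14 measured) for H3K4me1, 0.06 (12) for H3K4me3, 0.04 (11) for H3K27ac and -0.03 (11) for H3K36me3. After Bcl2l11 the highest H3K36me3 values were Bak1 at 0.17 and Bok at 0.14, and Bmf was lowest at -0.65 on 40 WT reads. For H3K27ac, Bbc3 (Puma) had -0.33 and Bmf -0.43. Among pro-survival genes, Mcl1 had 0.00 for H3K4me1, -0.21 for H3K27ac and 0.20 for H3K36me3, and Bcl2l1 had -0.05 for H3K4me3 and 0.05 for H3K36me3. The pro-survival H3K4me3 median of 0.61 lay at percentile 98.4 but rested on 7 measured members, most with few reads, it was -0.02 when centred over genes of similar mean, and it was within the range in 6 of 8 alternatives. Its lowest member Bcl2a1a and its high members Bcl2a1b and Bcl2a1d are nearly identical copies, so their separate folds are uncertain. The pro-survival H3K4me3 median of 0.61 is itself the value of Bcl2a1d, on 2 WT reads. Bcl2l10 at 0.81 rested on 2 WT reads too. The other medians of this list were within the range, at 0.15 for H3K4me1, -0.02 for H3K27ac and 0.17 for H3K36me3. Caspases and death receptors were within the random range for all marks, with H3K4me3 at 0.10, H3K27ac at 0.15 (percentile 97.2), H3K4me1 at 0.03 and H3K36me3 at 0.00. With the KO thinned to the WT reads, their H3K27ac median was 0.006 (percentile 48.1).

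The gene lists named for neutrophil granules had higher H3K4me3 in the KO, although not every listed gene encodes a granule protein. All 7 measured genes of the primary granule list lay above 0, with a median of 0.65 at percentile 99.99, which is the value of Serpinb1a. Random lists matched to this list had an H3K4me3 median of 0.15, so a value above 0 is not by itself a gain. Ms4a3 at 1.06 and the elastase gene Elane at 0.98 (on 7 WT reads) led, and Ctsg (cathepsin G) at 0.39 and Prss57 at 0.34 were lowest. Centred over genes of similar peak density, the list median was 0.24 (percentile 98.4). The myeloperoxidase gene Mpo had 0.43. All 11 measured genes of the secondary and tertiary granule list lay above 0 as well. Their median of 0.30, which is the value of Ltb4r1, was above all 10000 random lists, whose own median was 0.03. They ran from Cd177 at 0.54 and Chil3 at 0.52 to Lcn2 at 0.20 and the gelatinase gene Mmp9 at 0.11. Centred on the running median, Cd177 had 0.44, Lcn2 0.10 and Mmp9 0.01. For H3K36me3 the secondary list was slightly higher, at 0.05 (percentile 99.8), from Lcn2 at 0.21 and Ltf at 0.18 to Padi4 at -0.07 and Mmp8 at -0.08, while the primary list at 0.14 (4 measured, percentile 94.2) was within the range. With the nearest peak only, the primary list had 0.39 for H3K36me3 (percentile 99.1), beyond the range. H3K27ac of the primary list had a median of 0.30 (percentile 98.9), with Prtn3 at 0.52, Ctsg at 0.40, Serpinb1a at 0.00 and Ms4a3 at -0.12, and that of the secondary list was -0.02. In H3K4me1 both stayed within the range, at 0.01 and 0.02. The mature neutrophil list had an H3K4me3 median of 0.14 (percentile 99.0), with 15 of 16 above 0, led by Ncf1 at 0.38 (0.27 with the running median) and Cebpe at 0.37 and ending with Cxcr4 at 0.03 and Cebpd at -0.01 (-0.13 with the KO thinned). It was within the range for H3K27ac at -0.10, for H3K4me1 at 0.02 and for H3K36me3 at -0.01. With peaks within 1 kb of the start, the primary list had an H3K4me3 percentile of 94.1 and lost its place beyond the range. The primary list for H3K27ac lost it too, as well as with the nearest peak only and with the KO thinned to the WT reads, and the mature neutrophil list for H3K4me3 lost it with the 1 kb rule and with the running median.

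Immediate early and inflammatory genes carried less H3K27ac in the KO. Of 21 measured immediate early and stress genes 1 lay above 0, with a median of -0.23 at percentile 0.01, and the lowest were Atf3 at -0.79 and Fos at -0.59, ahead of Dusp1 at -0.56 and Fosb at -0.48. Hspa1a, a heat shock gene, was highest at 0.08, then Egr2 at -0.04. The same list had an H3K4me1 median of -0.08 at percentile 0.04, with 4 of 23 above 0 and values from -0.47 at Hsph1 to 0.10 at Jun and 0.55 at Hspa1a (on 24 WT reads), whereas its H3K4me3 median of 0.09 and its H3K36me3 median of -0.11 were within the range. NF-kB and inflammatory cytokine genes had an H3K27ac median of -0.19 at percentile 0.05, with 5 of 25 above 0. Cxcl1 at -0.65 (on 10 WT reads) and Ptgs2 at -0.56 were lowest and Nlrp3 had -0.54, while Cd14 at 0.75 and Tlr4 at 0.20 were highest. For this list H3K4me3 at 0.16, H3K4me1 at 0.07 and H3K36me3 at -0.04 were within the range. These H3K27ac and H3K4me1 placements held under every alternative tried.

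Interferon-stimulated genes had a higher H3K4me3 median of 0.20 (percentile 99.8), with 18 of 24 above 0, from Ifit1 at 0.63 and Oasl1 at 0.57 down to Isg20 at -0.17 and Isg15 at -0.19 (-0.37 with the KO thinned). This median was 0.10 when centred over peak density and 0.36 with peaks within 1 kb of the start, beyond the range in both. Their medians were within the range for H3K27ac at 0.05, H3K4me1 at -0.02 and H3K36me3 at -0.03. Cell cycle genes were higher for H3K4me3, with a median of 0.18 (percentile 99.9) and 18 of 24 above 0, and slightly higher for H3K36me3, with 0.04 (percentile 99.3) and 13 of 19. Matched random lists had H3K4me3 medians of 0.06 for the interferon list and 0.03 for the cell cycle list. Cdc6 at 0.43 and Aurkb at 0.40 led the H3K4me3 values, and Mcm3 at -0.23 and Ccne1 at -0.32 ended them. For H3K36me3 the cell cycle values ran from Pcna at 0.17 to Cdk1 at -0.14. Cell cycle medians for H3K4me1 (0.04) and H3K27ac (0.13) were within the range. The survival cytokine list was within the range for all marks (-0.01, 0.02, -0.07 and -0.02 in the order H3K4me1, H3K4me3, H3K27ac, H3K36me3). One of its members stood out. Csf2rb2, encoding a beta chain of cytokine receptors, had 1.06 (0.70 to 1.44) for H3K4me3, 0.51 (0.25 to 0.79) for H3K4me1, 0.37 (0.01 to 0.75) for H3K27ac and 0.38 (0.25 to 0.51) for H3K36me3. Its close relative Csf2rb had 0.57 for H3K4me3 and 0.27 for H3K27ac. Reads of these relatives may be shared in part, which was not tested, so both values are uncertain.

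Other lists gave small values. The genes around Bcl2l11 had a median beyond the range for H3K4me1 (0.14) and H3K36me3 (0.06) and within it for H3K4me3 (0.08) and H3K27ac (0.20), and this list holds Bcl2l11 and Gm14005 themselves. In H3K4me1 its other ends were Mall at 0.41, Zc3h6 at 0.40 and Ttl at -0.50, and in H3K36me3 Acoxl at 0.85 (on 14 WT reads), Zc3h6 at 0.83 and Zc3h8 at -0.19. The 2 H3K36me3 peaks of Acoxl are also counted in the Bcl2l11 sum outside the interval. The placement was lost in 3 of 7 alternatives for H3K4me1 and in 4 of 7 for H3K36me3. Housekeeping genes were lower for H3K4me1 at -0.07 (percentile 1.10), from Pgk1 at -0.25 and B2m at -0.22 to Tfrc at 0.06 and Eef1a1 at 0.07, but not beyond the range with all annotated peaks or with the KO thinned (percentile up to 18.3). They were within the range for H3K4me3 at 0.09, H3K27ac at 0.02 and H3K36me3 at -0.02. Genes of the Polycomb repressive complex (0.12, -0.07, 0.02 and -0.06), p53 targets (-0.03, 0.09, -0.06 and 0.00) and cytosolic ribosomal proteins (-0.04, 0.06, 0.11 and 0.02) were within the range in the same order of marks. Of 103 list values computed, 17 were beyond the range, against 5.15 expected if all genes and lists varied independently. Some lists share genes, and genes of 1 list can vary together between any 2 sorts. The excess therefore does not show an effect of genotype.

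Markers of other blood cells gave little beyond the range. In H3K4me3, the mark in which the granule lists were higher, the medians were 0.15 for monocytes and macrophages, 0.13 for dendritic cells, 0.26 for B cells, 0.07 for T cells, -0.04 for NK cells, 0.12 for erythroid cells, 0.11 for megakaryocytes, 0.13 for basophils and mast cells (3 measured), 0.33 for eosinophils (2 measured) and 0.18 for stem and progenitor cells (percentile 96.7), all within the range. With the KO thinned to the WT reads, the basophil and mast cell median was 0.45 (percentile 99.975), beyond the range. In H3K36me3 the B cell list was higher at 0.70 (percentile 99.4), on 4 measured genes of which Blnk had 1.11 on 18 WT reads Ebf1 0.78 on 37 WT reads, Cd79b 0.61 and Bank1 -0.20. The basophil and mast cell list had 0.20 (percentile 97.6), with Mcpt8 at 0.62, Hdc at 0.23, Ms4a2 at 0.08 and Kit at -0.20, and it was within the range in 6 of 7 alternatives. With all peaks annotated to a gene, the B cell median was 0.04 at percentile 59.2, within the range. For H3K36me3 the other marker lists were within the range, at -0.04 for monocytes, 0.34 for dendritic cells, 0.00 for T cells, 0.18 for NK cells, 0.13 for erythroid cells, 0.09 for megakaryocytes and 0.04 for stem cells, and no eosinophil gene was measured. In H3K4me1 and H3K27ac every marker list was within the range, from NK cells at -0.39 to eosinophils at 0.51 for H3K27ac. Dendritic cells came nearest to the edge, with an H3K27ac median of -0.34 at percentile 2.51, but 0.03 at percentile 62.9 with the KO thinned.

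**Figure D3:**
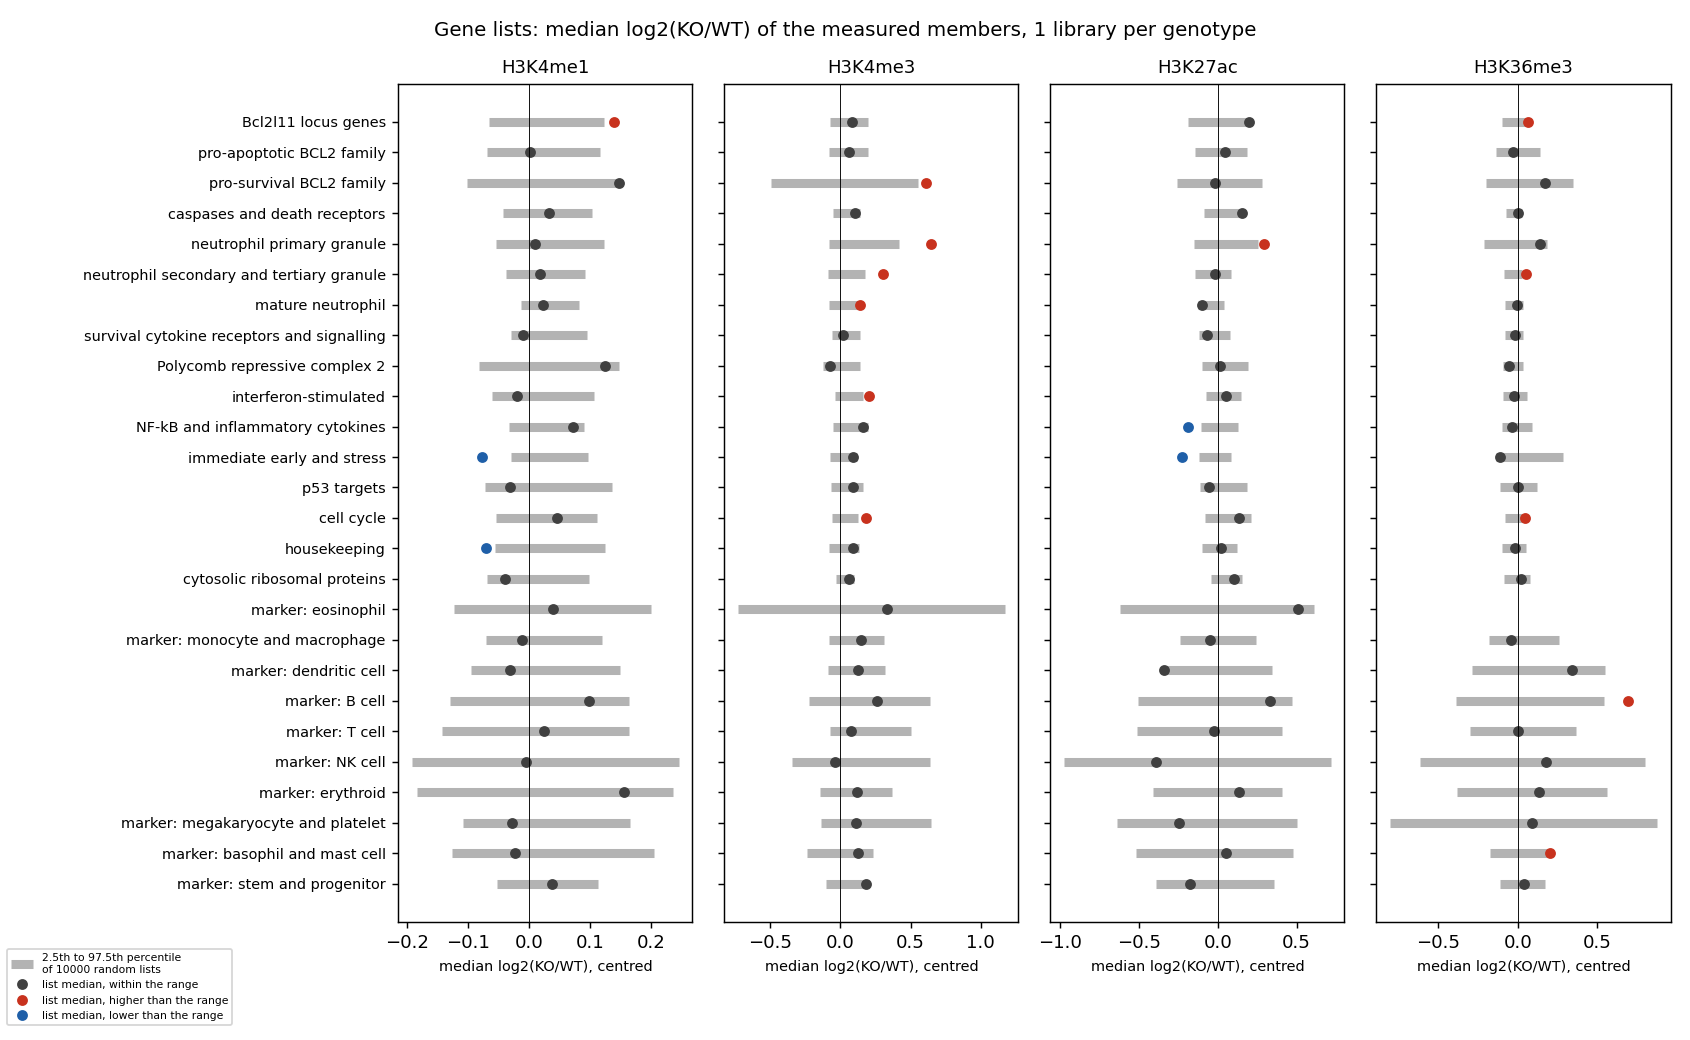
Median centred log2(KO/WT) of each gene list (points) and the central 95% of 10000 random matched lists (grey bars), one panel per mark with its own axis scale. For H3K4me3 the primary granule median of 0.65 lies right of its bar, and for H3K27ac the immediate early median of -0.23 lies left of its bar.

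Changes of the 4 marks were weakly related across genes. The Spearman correlation was 0.25 between H3K4me3 and H3K27ac over 11057 genes, 0.18 between H3K4me3 and H3K36me3 over 8628, 0.12 between H3K4me1 and H3K27ac over 11927, 0.10 between H3K4me1 and H3K4me3 over 13420, 0.07 between H3K4me1 and H3K36me3 over 9817 and 0.06 between H3K27ac and H3K36me3 over 8199. In genes at or above the median in both marks it was 0.01 for H3K4me1 and H3K4me3, 0.07 for H3K4me1 and H3K27ac, 0.10 for H3K4me1 and H3K36me3 and 0.26 for H3K4me3 and H3K36me3. Genes are not independent replicates. The median WT peak had 10 reads for H3K4me1, 7 for H3K4me3 and 8 for H3K27ac, and counting error can lower such correlations. Its share was not measured, so low values do not show that the marks change independently. Genes at least 2-fold higher in both H3K4me3 and H3K36me3 numbered 6, against 1.14 for independent lists, and 11 against 2.14 in both H3K4me3 and H3K27ac. Since 0 genes at or above the H3K4me3 median were 2-fold higher, all of these lay below it. Genes with few reads in both marks can overlap more than independent lists, so these overlaps do not show a shared change. Overlaps of lower genes (221 against 16.3 for H3K4me3 and H3K27ac) are raised by genes at 1 read in both libraries.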

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

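Alternatives without peaks at 1 read in both libraries, with genes of 3 reads or fewer removed, with the KO thinned to the WT reads, and with centring over peak density were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library per mark. The Bcl2l11 sums kept their sign under each alternative tried and left their counting interval once, for H3K4me3 centred on the running median (0.15). Counts of 2-fold peaks depended on weak peaks, given here as higher and lower for H3K4me1, H3K4me3, H3K27ac and H3K36me3 in turn. With a pseudocount of 10 they were 834 and 484, 720 and 221, 658 and 743, 80 and 284. Peaks at or above the median gave 271 and 128, 1062 and 120, 491 and 389, 8 and 56, and the 25% with the highest mean 7 and 8, 21 and 18, 11 and 22, 1 and 9. The running median gave 3166 and 2087, 1279 and 2299, 2779 and 2779, 616 and 2706. The 1.5-fold rule gave 11586, 9450, 10585 and 5386 higher, and 4263 lower for H3K36me3. Lower peaks numbered 4322, 1502 and 2891 without peaks at 1 read in both, and 3604, 1555 and 3204 with the KO thinned, for the first 3 marks.

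The number of lists beyond the random range became 1 for H3K4me1, 5 for H3K27ac and 3 for H3K36me3 with the KO thinned. The median of the genes around Bcl2l11 for H3K4me1 reversed with the nearest peak only (-0.0747) and with the KO thinned (-0.0122), and the pro-survival H3K4me3 median with the running median (-0.0217) and the density centring (-0.11). The cause was not tested. The Spearman correlation between H3K4me1 and H3K4me3 was 0.0106 in genes at or above the median in both, 0.0539 with the running median and 0.0474 without genes of few reads. Between H3K4me1 and H3K27ac it was 0.0660, 0.0606 and 0.0585 under the same settings and 0.10 with a pseudocount of 10, and between H3K4me1 and H3K36me3 it was 0.10 above the median. For H3K4me3 and H3K27ac it was 0.18 with the running median, 0.23 with a pseudocount of 10 and 0.19 without genes of few reads, and for H3K4me3 and H3K36me3 0.26 above the median and 0.15 with the running median. Of the other values, 1338 stayed within their spread and 37 moved without a change of sign that counts as a reversal.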

Other observations

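Of the tests in this part, the centring of the granule lists over peak density was set out before its result was seen. The scan of windows and the other tests were chosen after the values had been seen.

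A second region, on chromosome 14, carried less of all 4 marks in the KO. In 7038 windows of 200 kb with at least 100 WT reads per mark, 0 were at least 1.25-fold higher in all 4 marks and 5 were lower. Of those 5, 2 overlapped the deleted interval, 2 covered Slc25a37, Entpd4 and Loxl2, and 1 lay on chromosome 9 at Cdon and 4933422A05Rik. Over the chromosome 14 block, from about 69872684 to 70090561 (mm9), the log2(KO/WT) was -0.67 (counting interval -0.75 to -0.59) for H3K4me1, -0.60 (-0.71 to -0.48) for H3K4me3, -0.51 (-0.62 to -0.41) for H3K27ac and -0.99 (-1.09 to -0.90) for H3K36me3. All 15 H3K4me1 peaks, 10 of 11 H3K4me3 peaks, 15 of 18 H3K27ac peaks and 21 of 22 H3K36me3 peaks lay below 0. Peaks just after the block, up to 70592073, had a log2 of 0.09 for H3K4me1, 0.21 for H3K4me3, 0.05 for H3K27ac and 0.08 for H3K36me3. Slc25a37 encodes a mitochondrial iron importer and Loxl2 a lysyl oxidase.

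Over peaks at or above the median value, the medians of the X chromosome and of the autosomes were 0.03 and 0.02 in H3K4me1, 0.19 and 0.14 in H3K4me3, 0.08 and 0.06 in H3K27ac, and -0.01 and -0.04 in H3K36me3.

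For the lower signal from Slc25a37 to Loxl2, H3K36me3, whose libraries had similar depth, was lower as well. The scan that singled out this block required H3K36me3 to be lower too, so its value there is no independent test of unequal depth. In the 2 windows of the block chosen on the other 3 marks alone, its upper counting bounds were -1.15 and -0.45, and the other windows outside the deletion chosen the same way had a log2 of -0.10 (-0.25 to 0.05, chromosome 2 from 98400001), -0.17 (-0.31 to -0.03, chromosome 9 from 2900001) and -0.33 (-0.75 to 0.08, chromosome 9 from 35100001). Fewer DNA copies in the KO cannot be told apart from a change of the marks: the lower bound of H3K27ac lay 0.28 above the upper bound of H3K36me3, but the spread of such gaps between single libraries is not known. Variation between animals or sorts stays open too, because each genotype has 1 library per mark and 3 windows outside the deletion met the rule. A difference tied to genotype is the biological alternative, and it may be a change in the state of the sorted neutrophils, which was not tested.

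The higher signal over Bcl2l11 up to the deletion was weighed against depth, extra DNA copies and variation between animals. After centring on the running median and after thinning, the lower of the 2 lower counting bounds of the H3K36me3 value was 0.82. This argues against depth and the minimum for H3K36me3 only, since its libraries differed little in depth. The sums of the 3 marks of unequal depth were not part of this test, though they kept their sign under each alternative tried. Extra copies of the DNA cannot be told apart from other causes: at the promoter the lower bound of H3K27ac lay 0.36 above the upper bound of H3K4me1, but these bounds hold counting error only. Variation between animals or sorts cannot be told apart from genotype, since the rank of 1 among genes of similar sum comes from 1 library per genotype. A hypothesis left open is that loss of Morrbid or of the deleted DNA may raise transcription of Bcl2l11 in cis, and these data cannot separate the RNA from the DNA.

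The higher H3K4me3 of the granule lists was first weighed against a gain in broad, less dense peaks of any gene. After centring over genes of similar peak density the lower of the 2 list percentiles was 98.4, and with the KO thinned to the WT depth it was 99.8, so neither explains the lists as a whole, though the density centring brought the primary granule median from 0.65 to 0.24. A larger share of immature neutrophils in the KO sort may also raise them. It predicts higher H3K36me3 at both granule lists and cell cycle genes, where 2 of the 3 lists were above the random range. The primary granule list (4 measured, all above 0) was within the range at 0.14. With the nearest peak only it was beyond the range at 0.39 (percentile 99.1), so this part depends on the assignment of peaks. Cd101, a surface protein of mature neutrophils, was lower for H3K4me3 (-0.70) and H3K36me3 (-0.55), while the mature neutrophil list was higher than random lists for H3K4me3 (0.14, but not with the 1 kb rule or the running median) and within the range for H3K27ac (-0.10) and H3K36me3 (-0.01). Maturity and genotype cannot be told apart with 1 sort per genotype.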
